A study of Mus musculus with 10 samples.

How the data were processed

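Chromatin of mouse embryonic stem cells was profiled with and without BAF250a, the product of Arid1a and a subunit of the BAF (SWI/SNF) chromatin remodelling complex. Per the labels' protocols, the cells were grown on embryonic fibroblast feeders. Cells called KO received 1 µM 4-hydroxytamoxifen for 36 hours, starting 4 hours after passage, and cells called WT received ethanol on the same schedule, so genotype and drug exposure coincide in every sample. For ChIP, cells were fixed in 1% formaldehyde for 10 minutes, chromatin was cut with micrococcal nuclease and brief sonication, and 50 bp reads were sequenced. The 10 samples comprise 1 H3K4me3 library, 1 H3K27me3 library, 1 input library and 2 micrococcal nuclease libraries per genotype. The 4 ChIP libraries were analysed; nuclease and input profiles of their own were not used here.

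The values are 4 lists of enriched intervals (islands), 1 per ChIP library. The submitters' processing notes name Bowtie without a version, SICER version 1.1 and the mouse build mm9. The deposited lists carry a window of 200 bp, a gap of 200 bp for H3K4me3 and 600 bp for H3K27me3, and an FDR of 0.05. Read filters and treatment of duplicate reads are not given in the sources used here. Each island has a deposited ChIP read count and a deposited control read count, neither scaled. The deposited fold of an island equals its ChIP reads over its control reads multiplied by 1 constant per list, with 0.25 in place of a control count of 0. The deposited p-value equals a Poisson tail of those counts in 100% of islands, and the deposited adjusted p-value follows from it. Within each genotype, intervals identical in both marks carried equal control reads, 11 of 11 in WT and 4 of 4 in KO, so the same input served both marks. The constant was 1.78 for WT H3K4me3, 1.35 for KO H3K4me3, 1.68 for WT H3K27me3 and 1.03 for KO H3K27me3, and gives the ChIP to input depth ratio.

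Positions are given 1-based in mm9, with 1 added to each start and end in the lists. Library totals are not stated in them, so the depth of WT relative to KO is unknown and only reads inside islands are counted. A place without an island has no count, which differs from a count of 0. Islands were called shared when they overlapped by 1 bp or more. WT and KO islands of a mark were merged into regions, and reads of each library were summed per region. In regions with islands in both libraries and 20 or more reads in each, the KO over WT read ratio was taken after division by its total over all shared regions ("scaled reads"). The same regions were also compared by fold over input, recomputed from the summed read counts and the constant of each list. Intervals are 95% exact binomial (Clopper-Pearson) for shares, exact conditional binomial for ratios of counts, normal on the log scale for ratios of folds and rank-based for medians. Those for ratios cover read counting error only. Those for shares and medians treat the islands or regions of a list as independent draws. None covers the spread between libraries. With 1 library per genotype and mark, no p-value between genotypes was computed. Each comparison compares those libraries, not the conditions.

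A H3K4me3 island that overlapped a H3K27me3 island of the same genotype was called bivalent. To place the median of a class of regions, 10000 random sets of the same size, matched on read level, or on fold for the widest regions, in 20 bins, were drawn from the same regions. For the widest regions, sets were also drawn in 3 fold bins from the other strongly marked regions alone. This describes these libraries and is not a test of genotype. Regions named in the text follow a rule set before the data were examined. Per mark, the rule takes the 5 regions with the highest and the 5 with the lowest scaled read ratio among those with 100 or more reads in each library. It also takes the 5 regions with most reads among those called in 1 genotype with no island of the other within 5 kb. Any region outside this rule is said to have been chosen after its values were seen. Promoter states, the fixed gene lists and a check of the deleted Arid1a exons were not analysed here, because they need a gene annotation of mm9; the gene table at hand is of another build, and no coordinates were converted.

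Alternatives set before the data were examined were an overlap of 50% of the smaller island, an FDR of 1e-05, a fold of 2 or more, equal numbers of islands per mark, other scalings, other read minimums and autosomes alone. Added after the data were seen were intervals identical in both genotypes, estimates of depth from input reads, input reads per kb by chromosome, and removal of islands with input density above 3 times the median of their list. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Overlap counts were checked against bedtools 2.31.1 and differed by 0 islands. The ratio calculation was tested on simulated data with 200 regions raised and 200 lowered 2-fold. The simulated KO islands kept the WT intervals, so changes in called length, or islands called in 1 genotype only, were not tested. The recovered medians were 0.99 and −1.00 (log2) among 28365 simulated H3K4me3 islands, and 0.98 and −1.02 among 8067 simulated H3K27me3 islands.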

Results

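H3K4me3, a mark of promoters, and H3K27me3, the mark laid down by Polycomb repressive complex 2, were mapped in embryonic stem cells with BAF250a (WT) and after its deletion (KO), to ask how loss of this remodeller subunit alters histone marks. There was 1 library per genotype and mark, with no replicates, so none of the differences below could be set against a replicate spread. The H3K4me3 islands held 9565481 ChIP reads over 101.4 Mb in WT and 13512350 over 147.5 Mb in KO, or 94.3 and 91.6 reads per kb. The H3K27me3 islands held 1140878 reads over 35.4 Mb in WT and 839422 over 36.1 Mb in KO, or 32.2 and 23.3 reads per kb.

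H3K4me3 was called at more places in the KO library. It had 40978 islands against 28365 in WT, and 2717 against 1222 islands of 10 kb or wider, while the median island was narrower in KO (2000 bp) than in WT (2400 bp). Nearly all WT islands were present in KO, 26850 of 28365 (94.7%, 95% interval 94.4 to 94.9%), while 24417 of 40978 KO islands overlapped a WT island (59.6%, 59.1 to 60.1%). The 16561 KO islands without a WT island were small, with a median of 47 reads, 1200 bp and 2.36-fold over input, and held 7.59% of the KO island reads. The 1515 WT islands without a KO island had a median of 35 reads and held 0.70% of the WT island reads. Among the 10% of KO islands with the fewest reads, 12.9% overlapped a WT island, and among the 10% with the most, 99.95% did. When the KO list was cut to the 28365 islands with most reads, the length of the WT list, 6287 KO islands and 3302 WT islands lacked a partner.

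**Figure D1:**
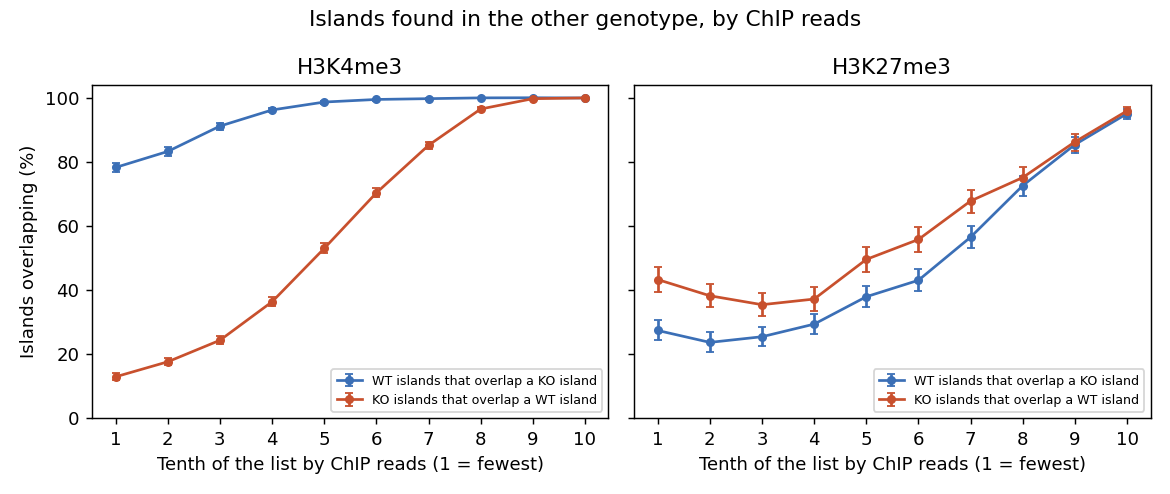
Share of islands (%, vertical axis) that overlapped an island of the other genotype, for 10 equal parts of a list ordered by ChIP reads (horizontal axis), with 95% exact binomial intervals that treat islands as independent draws. KO H3K4me3 islands ranged from 12.9% to 99.95%, WT H3K4me3 islands from 78.3% to 100%, and both H3K27me3 lists ended near 95% in the part with most reads.

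The KO-only H3K4me3 regions with most reads lay at chromosome 13, 53268801 to 53291400 (1208 reads, 2.89-fold over input), chromosome 1, 183890001 to 183912800 (1017 reads, 4.29-fold), chromosome 10, 76585001 to 76605000 (896 reads, 2.23-fold), chromosome 6, 136410601 to 136425000 (841 reads, 3.63-fold), and chromosome 8, 122854001 to 122862000 (774 reads, 4.05-fold). Each was 1 island of 8 to 22.8 kb with no WT island within 5 kb and no H3K27me3 island in either genotype. They are the top of 11701 KO-only regions with no WT H3K4me3 island within 5 kb, with or without H3K27me3. The 5 WT-only regions with most reads were of another kind. They were 1.03 to 1.63-fold over input, and 4 of them lay on the sex chromosomes, led by Y, 2779601 to 2797400, with 2711 ChIP and 1473 input reads. All 5 also carried a WT H3K27me3 island.

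Where H3K4me3 was called in both genotypes, enrichment over input was higher in the KO library. Over the 23385 shared regions the pooled fold over input was 4.19 in WT and 6.38 in KO. The median log2 KO over WT fold was 0.66 (95% interval 0.66 to 0.67), and 91.5% of 23281 regions were higher in KO. KO islands were wider in 70.6% of the 19936 regions with 1 island in each list and narrower in 19.8%, with median widths of 3200 and 2400 bp. At 1004 intervals with identical ends in both lists, where width plays no part, the fold was 3.57 in WT and 5.85 in KO, a ratio of 1.64 (1.61 to 1.67). Scaled to the reads in shared regions, which removes any change common to all of them, the median was 0.04 (0.04 to 0.05), and 54.3% of regions were higher in KO. Shared regions held 1.31 times as many reads in KO over 1.22 times the called length, at 95.5 reads per kb in WT and 102.5 in KO.

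Each of the 5 shared regions with the highest H3K4me3 ratio held 1 long KO island, of 11.8 to 44.8 kb, where 1 to 5 WT islands covered 3.6 to 10.4 kb. At chromosome 13, 44878401 to 44917000, 3 WT islands of 6.8 kb in all held 211 reads, and 1 KO island of 38.6 kb held 1999 reads, a log2 ratio of 2.85 (2.64 to 3.06) with folds over input of 2.52 and 4.82. At chromosome 4, 130237801 to 130282600, 5 WT islands of 10.4 kb held 281 reads and 1 KO island of 44.8 kb held 2134, with folds of 2.26 and 4.02. At chromosome 2, 10253601 to 10265400, reads went from 119 to 838 and fold from 1.97 to 5.82, and the H3K27me3 island present there in WT was not called in KO. At chromosome 11, 8463201 to 8481600, the folds were 1.75 and 3.06, whereas on X, 166419201 to 166447200, the fold was lower in KO, 1.33 against 1.42. Reads outside islands are not counted, so these ratios also hold the change in called length.

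The lowest H3K4me3 ratios lay between −2.21 and −1.64 on the log2 scale. On X, 123302001 to 123308800, reads went from 324 to 106 and the fold over input from 4.24 to 1.21, with 43 input reads over 6.8 kb in WT and 65 over 3.4 kb in KO. At chromosome 4, 145145201 to 145150000, the folds were 2.25 and 1.24, with 63 input reads over 4.8 kb in WT and 61 over 2 kb in KO. At chromosome 12, 75045601 to 75052800, they were 7.17 and 5.51. The other 2 regions, at chromosome 17, 31015201 to 31021000, and chromosome 12, 77171401 to 77175800, had slightly higher folds in KO (3.20 and 3.72 at the first, 2.85 and 3.06 at the second), so their direction turned with the scaling.

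**Figure D2:**
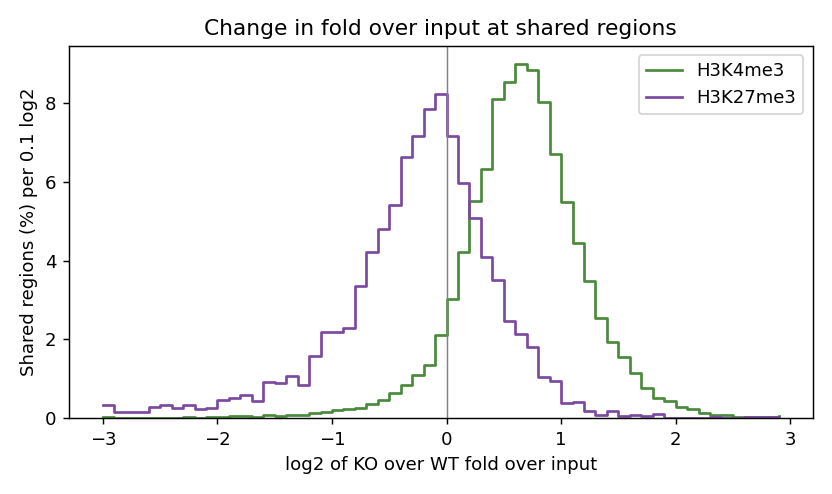
Distribution of the log2 KO over WT ratio of fold over input (horizontal axis) over shared regions with 20 or more reads in each library, as percent of regions per 0.1 log2 (vertical axis), values beyond 3 set to 3. The H3K4me3 curve centres at 0.66 and the H3K27me3 curve at −0.18; with reads scaled to shared regions the medians were 0.04 and 0.08.

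H3K27me3 was called at fewer places in the KO library, and about 50% of the WT islands had a KO partner. There were 8067 islands in WT and 6833 in KO, covering nearly the same length. Of the WT islands, 4004 overlapped a KO island (49.6%, 48.5 to 50.7%) and 4063 did not, and of the KO islands, 3994 overlapped a WT island (58.5%, 57.3 to 59.6%) and 2839 did not. Islands with many reads were shared far more often: in the 10% with most reads, 95.0% of WT and 95.9% of KO islands overlapped. Islands found in 1 genotype had medians of 57 reads in WT and 64 in KO, and held 24.1% and 24.5% of the island reads. Their median fold over input was 3.22 against 2.50 for shared islands in WT, and 2.26 against 2.21 in KO. Islands were listed only if they passed an FDR on ChIP against control reads, so those with few reads needed a higher fold. These medians therefore do not show that unshared islands were as strong as shared ones.

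In the 3379 shared H3K27me3 regions the direction of the difference depended on the scaling and on the read minimum. Pooled fold over input was 2.24 in WT and 1.95 in KO, with a median log2 fold ratio of −0.18 (−0.20 to −0.15) and 64.1% of regions lower in KO. Scaled to reads in shared regions, which removes any change common to all of them, the median was 0.08 (0.05 to 0.12). By that measure 54.3% of regions were higher in KO. With 100 or more reads in each library the scaled median was −0.045. The KO total in these regions was 0.732 of the WT total over 1.03 times the called length, at 36.2 and 25.7 reads per kb. Input reads per kb in the same regions were 1.33 times as high in KO (1.33 to 1.34), whereas over shared H3K4me3 regions they were 0.933 times as high (0.931 to 0.935).

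Of the 5 shared regions with the highest H3K27me3 read ratio, 4 lay on chromosome 14 between 4129601 and 8419800, with KO folds of 1.49 to 1.73, and the remaining one at chromosome 8, 72053401 to 72064000, had a fold of 4.33 in WT and 1.29 in KO. At chromosome 14, 8400801 to 8419800, reads went from 107 to 462 and the fold from 1.88 to 1.71. The 5 lowest ratios, log2 −2.29 to −1.69, included chromosome 8, 126061401 to 126153200 (3205 and 481 reads, fold 1.16 in KO and lower in WT), and chromosome 4, 145251601 to 145298400 (1762 and 373 reads, folds 2.26 and 2.12). In 4 of these 5 the fold was higher in KO. The 5 WT-only regions with most reads had folds of 1.17 to 2.68; chromosome 1, 24618201 to 24623200, led with 1131 reads at 1.17-fold, chromosome 18, 80194001 to 80208400, had 423 reads at 2.68-fold, and chromosome 11, 96259001 to 96274200, had 378 reads at 1.48-fold. The 5 KO-only regions with most reads, among them chromosome 8, 56196201 to 56209200, with 953 reads, had folds of 1.12 to 1.45.

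The long, strongly marked H3K27me3 regions had lower values in KO. The 10 widest regions with a mean fold of 2 or more, with regions of high input density left out, were chosen after their values were seen. Input per kb still differed between the genotypes in some of them, as given below. In 8 of them scaled reads were lower in KO, at 0.576 to 0.871 of WT. Pooled over all 10 the scaled ratio was 0.742 (0.731 to 0.753) and the fold over input 3.03 in WT and 2.26 in KO. The longest spanned chromosome 15, 102752601 to 102908600, with 9754 reads and a fold of 3.10 in WT and 4618 reads and 2.41 in KO. Chromosome 6, 52091401 to 52230400, had 9441 and 3980 reads and folds of 3.05 and 2.16. Chromosome 11, 96103001 to 96248600, had 8936 and 3942 reads and folds of 2.85 and 2.20. H3K27me3 formed 12 islands in WT and 31 in KO over these 8 regions, and 23 and 33 over all 10. Scaled reads per kb were also lower in KO in 76 of 90 other regions with 500 or more reads in each library and a mean fold of 2 or more. The exception by fold was chromosome 4, 114561801 to 114612400, at 2.11 in WT and 2.15 in KO. The 2 of the 10 regions with higher scaled reads in KO adjoin each other at chromosome 13, 12865601 to 13062800, with 5 and 6 H3K27me3 islands in WT and 1 each in KO; there the fold was lower in KO and input per kb 2.47 and 2.48 times that of WT.

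H3K4me3 inside the 10 regions was called at 64 islands in WT and 76 in KO, in opposite directions by place. The 2 chromosome 13 regions had 10 and 14 islands in WT and 0 in KO, and the other 8 together 40 in WT and 76 in KO. On chromosome 6 the islands went from 7 to 19 and their reads from 1210 to 3634, a ratio of 2.28 (2.14 to 2.44) after scaling. Single islands there held 30.6 to 70.9 reads per kb in WT and 28.9 to 75 in KO, not scaled for depth. The chromosome 11 region had 5 and 15 islands and a scaled ratio of 2.17 (2.01 to 2.33), and the chromosome 15 region 11 and 19 islands and 1.35 (1.27 to 1.44). The interval of the scaled ratio lay above 1 in 4 of these 8 and spanned 1 in the other 4. These ratios sum reads only inside called islands, so they also hold the change in called length. They do not by themselves show a gain of the mark.

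**Figure D3:**
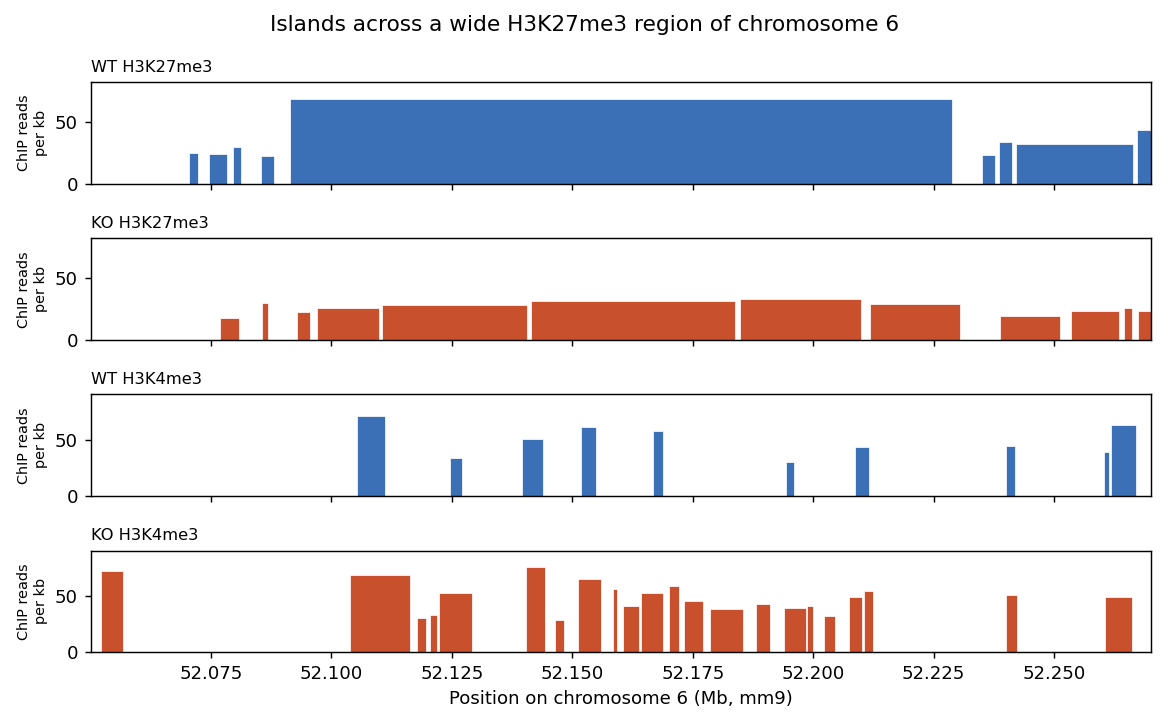
Islands of both marks around the wide H3K27me3 region of chromosome 6 (mm9 position in Mb, horizontal axis), drawn to scale with height as ChIP reads per kb of the island (vertical axis, not scaled for depth). The WT H3K27me3 island at 68.7 reads per kb faces 6 KO islands at 22.9 to 33.2 reads per kb, and H3K4me3 islands inside the region number 7 in WT and 19 in KO.

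Bivalent islands, with both marks, numbered slightly fewer in KO, and the share of WT bivalent islands with both marks in KO depended on the overlap and fold required. There were 3054 in WT (10.8% of H3K4me3 islands, 10.4 to 11.1%) and 2780 in KO (6.78%, 6.54 to 7.03%), the lower share going with the longer KO H3K4me3 list. Taken from the other mark, 37.4% of H3K27me3 islands overlapped H3K4me3 in WT (36.3 to 38.5%) and 41.9% in KO (40.7 to 43.0%). Of the WT bivalent islands, 1835 overlapped both marks in KO (60.1%, 58.3 to 61.8%), 901 H3K4me3 alone (29.5%, 27.9 to 31.2%), 257 H3K27me3 alone (8.42%, 7.45 to 9.46%) and 61 neither (2.00%, 1.53 to 2.56%). In all, 962 had no H3K27me3 and 318 no H3K4me3 island in KO. Absence of H3K27me3 in KO was not particular to bivalent islands, as 4063 of all 8067 WT H3K27me3 islands had no KO partner. WT H3K27me3 islands with H3K4me3 had a KO partner more often (66.2%, n = 3016) than those without (39.7%, n = 5051). In the 20% with fewest reads these shares were 25.1% and 25.6%, and in the 20% with most 91.8% and 85.9%. Of the KO bivalent islands, 1857 overlapped both marks in WT and 923 did not (33.2%, 31.5 to 35.0%). With a fold of 2 or more required in every list, the bivalent counts were 1398 in WT and 1401 in KO, and 46.5% of the WT islands (43.9 to 49.2%) overlapped both marks in KO. With an overlap of 50% of the smaller island it was 42.5% (40.5 to 44.5%).

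Among WT H3K4me3 islands with few reads, calls were lost more often at bivalent islands than at others. Part of this loss lay in 3 segments where KO input per kb was higher in H3K27me3 regions. These segments, chosen after the values were seen, lay on chromosome 4 (145017201 to 147979000), X (120098001 to 122876600) and chromosome 13 (12856801 to 13034600). At all read levels together they held 148 of the 318 bivalent islands lost. In the 20% of WT H3K4me3 islands with fewest reads, 46.4% of bivalent islands (41.2 to 51.7%, n = 366) overlapped a KO island, against 83.1% of the others (82.1 to 84.1%, n = 5307). In the next 20% the shares were 81.8% and 94.7%, and in the 20% with most reads 99.4% and 100%. Without the 3 segments the share in the lowest 20% was 56.4% of bivalent islands (50.2 to 62.4%, n = 266) against 83.1%, and in the next 20% 90.3% against 94.7%. With islands ordered by fold over input in place of reads, and the segments left out, the intervals of bivalent and other islands overlapped in the lower 4 of 5 equal parts (shares of 92.2 to 96.1% and 93.3 to 96.5%), and in the highest part the shares were 87.1% (82.3 to 91.0%) and 96.0% (95.4 to 96.5%). Taken from the KO list the direction was the opposite. Of bivalent KO H3K4me3 islands, 81.1% overlapped a WT island (n = 2780), against 58.0% of the others (n = 38198). In the 20% of KO islands with fewest reads the shares were 37.4% and 14.7%, and in the 20% with most 100% and 99.8%. At shared regions, H3K4me3 with a WT H3K27me3 island had a median log2 scaled read ratio of −0.12 against 0.06 elsewhere, and a fold ratio of 0.63 against 0.67. Both medians lay below all 10000 read-matched sets, whose medians ran from 0.01 to 0.10 and from 0.67 to 0.75. For H3K27me3 at shared regions with a WT H3K4me3 island, scaled reads were lower than elsewhere (−0.16 and 0.50) but the fold ratio was higher (−0.09 and −0.33), so no direction can be given. Median log2 KO over WT input per kb was 0.23 in these regions and 0.75 elsewhere, so the fold ratio also holds that difference in input.

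Input reads in shared regions were compared by chromosome, relative to all autosomes, to look for differences in copy number or input. As sums over islands, the KO over WT ratio was at most 1.05 on any autosome in H3K4me3 regions (chromosome 16, 1.04 to 1.07). In H3K27me3 regions the sums gave 1.69 on chromosome 14, but called length there was 1.44 times as long in KO, and per kb the ratio was 1.21 (1.19 to 1.23). Per kb in H3K27me3 regions, chromosome 1 was the highest autosome at 1.25 (1.22 to 1.27) and chromosome 11 the lowest at 0.804 (0.783 to 0.825), with 1.76 (1.71 to 1.81) on X. For X the H3K4me3 regions gave 1.03 (1.01 to 1.04) per kb. Input inside islands is read only where islands were called, so these ratios do not give copy number.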

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

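Intervals identical in both genotypes, input per kb by chromosome, depth estimates and removal of high input density were chosen after the data were seen; the other settings were planned. Of all alternatives, 45 left a result within its interval or within 1.5 times its count, 14 moved it and 9 reversed its sign; the causes were not tested, except where a setting shortens a list. Requiring 50% overlap gave 1802 bivalent islands in KO. Requiring a fold of 2 gave 1398 bivalent islands in WT and 1401 in KO. With equal list lengths, 6287 KO and 3302 WT H3K4me3 islands were unshared. Both counts moved because the KO H3K4me3 list was shortened, while the WT H3K4me3 list stayed whole. Counts under the FDR of 1e-05 stayed within 1.5 times the main ones.

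The H3K4me3 median at shared regions (log2 0.04) was 0.66 by fold over input, 0.66 by fold without high-input regions, 0.76 by fold at identical intervals, and 0.88, 0.42 or −0.064 with depth taken from input at identical H3K4me3 intervals, at shared H3K27me3 regions or at identical H3K27me3 intervals. It was −0.061 when scaled to all island reads and −0.055 with 100 or more reads per library. The H3K27me3 median (0.08) was −0.18 by fold over input, −0.17 by fold without high-input regions, −0.37 by fold at identical intervals, −0.045 with 100 or more reads, 0.051 on autosomes, and 0.38, −0.075 or −0.56 with the same depth estimates. Only 61 H3K27me3 intervals were identical in both lists, against 1004 for H3K4me3, and KO over WT input there was 1.87 (1.83 to 1.92). The −0.37, the −0.56 and the −0.064 of H3K4me3 rest on these 61 intervals. The highest autosomal input ratio of 1.05 became 1.69 in H3K27me3 regions, where called length differed, and 1.25 there per kb. How far depth limits each list is open, since no totals are stated; H3K4me3 over H3K27me3 depth was 1.06 in WT and 1.31 in KO.

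No paired analysis was possible because the numbered replicates are nuclease libraries, which were not analysed here, and each ChIP group has 1 library. Promoter and gene-list alternatives were not run for want of an mm9 annotation.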

Other observations

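Segments and explanations in this part, and their tests, were chosen after the results were seen. WT-only H3K4me3 islands crowded into a few segments. The stretches at chromosome 4, 145017201 to 147979000, X, 120098001 to 122876600, and chromosome 13, 12856801 to 13034600, held 77, 48 and 25 of the WT-only regions, together 9.90% of them but 0.755% of all H3K4me3 regions. In shared H3K4me3 regions KO input per kb was 1.53 (1.49 to 1.57) times that of WT in the first segment and 1.13 (0.915 to 1.39) times in the second, from 8 regions, and the last had no shared H3K4me3 region. In shared H3K27me3 regions of the 3 segments the ratios were 1.79 (1.75 to 1.84), 2.26 (2.19 to 2.33) and 2.53 (2.38 to 2.68). The chromosome 13 segment overlaps 2 of the 10 widest H3K27me3 regions, at 12865601 to 12952000 and 12955401 to 13062800. There the scaled H3K27me3 reads were 1.36 and 1.33 times as high in KO, the folds over input went from 3.50 to 2.17 and from 2.93 to 1.78, and 10 and 14 WT H3K4me3 islands faced 0 in KO.

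H3K27me3 islands of KO also crowded at the start of chromosome 14. Regions there up to 8593000 numbered 403, of which 225 were KO-only and 17 WT-only, and KO islands covered 2.85 Mb against 1.03 Mb in WT. Enrichment was low in both, with pooled folds of 1.81 in WT and 1.63 in KO, and input per kb was 9.33 and 14.2.

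The first pattern is the higher fold over input and larger number of islands of H3K4me3 in KO. A deeper KO library is argued against for the fold, which depth leaves at 1 and which was 1.64 times as high at identical intervals. For the island number depth stays open: 3 estimates of KO over WT depth from input reads ran from 0.736 to 1.42, and islands were 1.44 times as many. The highest estimate came from 61 identical H3K27me3 intervals. Input libraries of different composition stay open too, since the depth-scaled medians ran from −0.064 to 0.88 with the place where input was read. Stronger enrichment of the KO library as a whole cannot be told apart from a gain of the mark over the whole genome, or from an effect of tamoxifen, with 1 library each; on every autosome and X at least 89.5% of shared regions were higher by fold.

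The second pattern is the H3K27me3 direction that turned with the scaling. Scaling to reads in shared regions uses no input and removes any change common to all of them. Its median therefore gives no direction for the mark as a whole. Input does not enter this scaling, but control reads helped decide which islands passed the FDR. Input composition can therefore still bear on which reads were counted. Where depth was taken from input, the median was 0.38, −0.075 or −0.56 with the place where input was read. Input libraries of different composition may account for this turn. KO over WT input per kb at shared H3K27me3 regions was 1.37 times the ratio at identical H3K4me3 intervals. A change in the mark itself stays open, as no depth is stated that would fix the scale.

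The third pattern is the lower H3K27me3 of the 10 widest regions. Input composition is argued against as the whole cause in the 8 regions lower in scaled reads. There KO over WT input per kb was 1.04 (1.01 to 1.08) times that at identical H3K4me3 intervals, where 1.26 would be needed for the loss of fold. Before that division the ratio was 0.985 to 1.12 in the 8. Over all 10 it was 1.25 (1.22 to 1.29) where 1.34 would be needed, and most of that excess lay in the chromosome 13 pair. The margin over all 10 depends on the reference, as KO over WT input was 0.973 at identical H3K4me3 intervals and 0.933 per kb over shared H3K4me3 regions. Over all 10 input composition therefore stays open. Weaker enrichment of the KO H3K27me3 library as a whole stays open: among the other 90 regions with 500 or more reads in each library and a mean fold of 2 or more, 76 were also lower in scaled reads per kb, and the 10 widest lay at percentile 8.88 of fold-matched sets of them (1.73 and 0.49 with read minimums of 300 and 200, and 0.01 against all shared regions). By fold over input the percentiles were 3.04, 14.4 and 15.8 with minimums of 500, 300 and 200, and 27.3 against all shared regions, so the answer turned with the measure and the minimum. A loss of Polycomb marking after BAF250a deletion stays open and untested with 1 library per genotype.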
